A study of Homo sapiens with 41 samples.

How the data were processed

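Expression was measured on 41 Affymetrix Exon 1.0 ST arrays, 21 of K562 and 20 of GM12878, from 7 laboratories, with 3 arrays per laboratory and line and 2 for GM12878 from Affymetrix. Cell pellets were frozen or kept in Trizol, RNAlater or RLT buffer, and RNA was made with Trizol or RNeasy, per the labels' protocols, which do not say which array had which. The labels give the Affymetrix whole-transcript protocol with biotin labelling for all arrays. The array files themselves were not used here.

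The deposited values are log2 signals per transcript cluster, made by the authors with RMA in Affymetrix Expression Console, per the labels' processing notes. The versions, the probe set level, the background step and the genome build are not given in the sources used here. The table holds 22011 clusters and 41 arrays. Of these clusters 14432 carry 1 gene symbol, 2408 several and 5171 none. Counts of calls are over all clusters, and genes were named from clusters with 1 symbol, the cluster of highest mean standing for a gene with several, which gave 14223 genes. Of the symbols 14404 were matched by gene ID to the reference gene table, which was used for names and chromosomes alone.

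RMA leaves exactly equal values between arrays normalized together, and these were counted for every pair of arrays. Within each line and block of deposit numbers, the median pair shared 745.5 values (GM12878, the first block), 523 (GM12878, the second) and 625 (K562, the first), while no pair from different blocks or lines shared more than 3. The 10 arrays of the second K562 block shared 0 to 13. The 17 of their 45 pairs that shared more than 3 link all 10 arrays, while no array of this block shared more than 1 value with an array of the other K562 block, so they were taken as 1 run. Medians of array medians were 5.58 and 5.52 in the GM12878 runs and 5.78 and 5.95 in the K562 runs. All arrays from Albany and Duke lie in the first runs, and GM12878 from Affymetrix and Yale in the second.

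Tests were made with limma 3.58.1 in R 4.3.3, with Python 3.11.15 and matplotlib 3.10.9 for figures. For the comparison of the lines, arrays were averaged per laboratory and line, and the 14 means were fitted with laboratory as a block. For laboratories, all 41 arrays were fitted with 14 group means. Limma's F-test was taken over the 7 laboratories in each line and over the interaction, and each laboratory was set against the unweighted mean of the other 6 in its line. All tests were two-sided, with Benjamini-Hochberg adjustment over all clusters within a test. A call needs an adjusted p under 0.05 and an absolute log2 difference, or range of means, of at least 1. The SE beside a limma difference is the moderated standard error.

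The 31 gene lists, the comparisons, the rule for named genes and most alternatives were chosen before the data were examined. Of the lists 29 had at least 5 measured members and 2, small nucleolar RNA and mitochondrially encoded genes, had none. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests a list against 0 and not against the other genes, adjusted over lists (for laboratories over 406 pairs), and called members were counted adjusted over all clusters and adjusted over the list alone. The lists were erythroid, megakaryocyte, granulocyte and monocyte, B cell, plasma cell, T and NK cell, fibroblast and epithelial, MHC class II, MHC class I presentation, NF-kB targets, interferon response, 9p21, 9q34 and 22q11, STAT5 targets, ERK output, p53 targets, cell cycle, cancer testis, HOX, immediate early, heat shock, hypoxia, integrated stress response, unfolded protein response, cholesterol biosynthesis, histones, ribosomal proteins, metallothionein and oxidative stress, and housekeeping. Means of a list per array were compared with exact permutation tests, and relations across arrays with permutation tests of 100000 resamples.

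The named genes were the 10 called genes with the largest difference in each direction between the lines and the same sign in all 7 laboratories, the 10 with the widest range in each F-test, the 2 with the largest difference in each direction for each laboratory, and the 2 called members with the largest difference in each direction for each list. Clusters with several symbols, XIST, TSIX and genes on the Y chromosome were left out of the naming. Further members are named in places for the laboratory lists, and those were chosen after their values were seen.

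The limma comparisons were tested on simulated data with 200 of 22011 clusters changed, for laboratories in K562 alone. Noise was drawn independently for each cluster, without any spread that the clusters of 1 array or run share. The counts below therefore do not give the rate of false calls in the real arrays. Tests of lists and chromosomes and the permutation tests were not simulated. At log2 sizes of 0.5, 1 and 2 the adjusted p was under 0.05 for 2.99%, 46.3% and 92.4% of changed clusters in the comparison of the lines, 2.99%, 38.8% and 87.9% in the K562 F-test, 16.4%, 70.1% and 97% for 1 K562 laboratory against the others, and 0%, 16.4% and 75.8% in the interaction. Unchanged clusters with an adjusted p under 0.05, without the floor of 1, numbered 8, 4, 6 and 5. In the GM12878 F-test, where no cluster was changed, they numbered 0.

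Alternatives covered the block and unit of replication, the deposit block, filters on dim clusters, quantile normalization and median centring of the deposited values, limma's trend and robust options, the floor and the threshold, and leaving out arrays or laboratories. Those added after seeing the data were the runs taken alone, the upper quartile of each array as a covariate, and leaving out arrays with an upper quartile over 0.3 below their run's median. A second limit of 0.35 was tried after the counts with the first were seen. No sample was left out of the main comparisons.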

Results

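Gene expression was measured on 41 Affymetrix Exon 1.0 ST arrays in 2 human cell lines that each of 7 laboratories had grown. K562 is a chronic myeloid leukaemia line that carries the BCR-ABL1 fusion, and 21 arrays held its RNA, 3 from each laboratory. GM12878 is a B lymphoblastoid line made with Epstein-Barr virus, and 20 arrays held its RNA, 3 from each laboratory except Affymetrix, which gave 2. The other laboratories were at Albany, the Broad Institute, Duke, Stanford, Washington and Yale. Nothing in the labels says that the arrays of 1 laboratory came from separate cultures, so the spread between them may be technical, and p-values across arrays measure that spread alone. The number of arrays limits the precision of every value. Values are log2 RMA signals, 1 per transcript cluster, for 22011 clusters.

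The arrays bear on how far the lines differ and how far 1 line differs between laboratories. Storage and RNA method, unknown per array, may differ with laboratory and were not tested. Averaged over clusters, cell line accounted for 35% of a cluster's sum of squares and laboratory for 18.3%. The interaction of both held 11.4% and arrays within a laboratory and line 35.3%. These shares were not corrected for the number of groups, so spread between arrays alone adds to the laboratory and interaction shares. Across clusters, which are not independent replicates, arrays of different lines correlated at a mean r of 0.859 ± 0.013 (SD, 420 pairs). Within GM12878 and 1 deposit block, the mean r was 0.972 ± 0.020 (SD, 13 pairs) for arrays of 1 laboratory and 0.963 ± 0.017 (SD, 78 pairs) for arrays of different laboratories. The K562 values were 0.979 ± 0.014 (SD, 11 pairs) and 0.967 ± 0.013 (SD, 89 pairs). These pairs share arrays, and their difference was not tested.

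Red-cell genes stood higher in K562, and B-cell, antigen presentation and interferon genes stood higher in GM12878. HBZ, the embryonic zeta globin, stood at 9.81 ± 0.81 in K562 and 1.94 ± 0.17 in GM12878 (SD, n = 7 laboratories). RHAG, a component of the Rh complex of the red-cell membrane, stood at 10.78 ± 0.37 against 2.55 ± 0.10. HLA-DRA, the alpha chain of the class II molecule HLA-DR, stood at 2.89 ± 0.14 in K562 and 11.68 ± 0.42 in GM12878, and JCHAIN, which joins polymeric immunoglobulin, at 2.47 ± 0.21 against 10.46 ± 0.59. MX1, an antiviral GTPase induced by interferon, stood at 3.24 ± 0.14 against 10.58 ± 0.57.

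The comparison of the lines, with laboratory as a block, called 4777 clusters, of which 3325 were higher and 1452 lower in K562. The median of all clusters was itself 0.33 higher in K562, and differences between the lines are given below relative to that median. After quantile normalization of the deposited values the calls split into 1891 higher and 1903 lower, and after centring each array on its median into 2075 higher and 1890 lower. The 2 lines had been normalized apart, and so had the 2 blocks of arrays within each line, so every level set between the lines crosses runs.

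The 10 genes with the largest positive difference were CTCFL, the testis paralogue of the insulator protein CTCF, CPED1, RHAG, PRKAR2B, a regulatory subunit of protein kinase A, ALDH1A2, which makes retinoic acid, HBZ, ANXA1, a phospholipid-binding annexin, GALNT5, which starts O-glycosylation, NMU, a neuropeptide, and TMEM98. Their differences ran from 8.03 ± 0.13 (SE) for CTCFL, adjusted p = 1.68e-10, to 5.94 ± 0.15 for TMEM98, adjusted p = 1.42e-09. In GM12878 these genes stood at 1.94 (HBZ) to 2.91 (NMU). The lowest lower quartile of a GM12878 array was 3.42, so the sizes and order of these differences rest on values at the low end of the scale. The 10 with the largest negative difference were HLA-DRA, HLA-DPA1, the histone H3 gene H3C11, JCHAIN, IFI44L, SCIMP, an adaptor of antigen-presenting cells, CD48, PLEK, a substrate of protein kinase C, MX1 and CD74, the class II invariant chain. Theirs ran from -9.12 ± 0.16 for HLA-DRA, adjusted p = 3.83e-10, to -7.58 ± 0.10 for CD74, adjusted p = 1.07e-10. All but CD48 (3.77) and CD74 (4.68) stood in K562 below 3.50, the lowest lower quartile of a K562 array. The sizes and order of their differences rest on such low values too. The rule that picked these genes required the same sign in all 7 laboratories. All 20 were called under both other scalings.

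Among lists of genes fixed before the data were examined, red-cell genes were higher in K562. Of 29 measured erythroid genes, 22 were higher and 1, TSPAN33, was lower (median relative difference 2.91; camera adjusted p = 2.69e-05, adjusted p = 0.142 with an estimated correlation). The list near ABL1 on 9q34 and BCR on 22q11, the loci of the fusion, had 10 of 19 members higher (adjusted p = 0.00539, adjusted p = 0.138 with an estimated correlation), led by HIC2, a transcriptional repressor, at 3.23 ± 0.10 (SE) and NUP214, a nuclear pore protein, at 2.47 ± 0.11. Cell cycle genes of S and G2/M had 17 of 35 members higher and 1 lower, among them the mitotic kinesin KIF2C at 1.67 ± 0.18 and the kinase CDK1 at 1.53 ± 0.25, with UBE2C lower at -1.87 ± 0.11. That list's camera test gave adjusted p = 0.0419, and adjusted p = 0.770 with an estimated correlation, and it was not called over the clusters above the median mean signal (adjusted p = 0.0905).

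B-cell and antigen presentation genes were lower in K562. Of 30 B-cell genes, 26 were lower (median -3.93; adjusted p = 1.1e-28, and adjusted p = 0.0289 with an estimated correlation), led by IRF8, a lymphoid and myeloid transcription factor, at -7.28 ± 0.13 (SE) and FCER2, the low-affinity IgE receptor, at -6.80 ± 0.10. Of 28 NF-kB targets, 22 were lower (median -2.61; adjusted p = 4.29e-24, and adjusted p = 0.0289 with an estimated correlation), led by the chemotactic receptor GPR183 at -6.68 ± 0.19 and the death receptor FAS at -6.42 ± 0.14. Among the plasma-cell genes 8 of 12 were lower, JCHAIN and the transcription factor IRF4 most (adjusted p = 4.96e-10, adjusted p = 0.0893 with an estimated correlation). All 9 MHC class II genes were lower (adjusted p = 9.54e-13, adjusted p = 0.0893 with an estimated correlation), and 9 of 14 class I presentation genes were, led by the immunoproteasome subunit PSMB8 at -4.38 ± 0.30 and HLA-F at -3.87 ± 0.11 (adjusted p = 4.93e-11, adjusted p = 0.137 with an estimated correlation). Of 32 interferon response genes, 25 were lower, IFI44L and MX1 most (adjusted p = 8.02e-23, adjusted p = 0.142 with an estimated correlation).

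In 9p21, the region of the CDKN2A tumour suppressor, 3 of 8 measured genes were lower, with MLLT3, a subunit of the super elongation complex, at -5.23 ± 0.18 (SE) and KLHL9, a ubiquitin ligase adaptor, at -3.96 ± 0.10 (adjusted p = 0.00115, adjusted p = 0.0902 with an estimated correlation). Of 24 p53 targets 8 were lower, FAS and TIGAR, a fructose bisphosphatase, most, and 3 were higher, among them the sestrins SESN1 at 1.44 ± 0.10 and SESN2 at 1.12 ± 0.16 (adjusted p = 0.00177, adjusted p = 0.442 with an estimated correlation). Replication-dependent histone genes went both ways, 14 higher and 14 lower of 50. H2AC25 at 3.28 ± 0.25 and H2BC11 at 3.07 ± 0.24 led the first, and H3C11 at -8.67 ± 0.17 and H3C3 at -7.29 ± 0.20 the second (adjusted p = 0.0419, adjusted p = 0.770 with an estimated correlation). The histone list was not called after quantile normalization (adjusted p = 0.151) or centring (adjusted p = 0.305).

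The other 17 lists were not called by camera. Integrated stress response genes had 22 of 33 members higher and 1 lower, with CBS, a transsulfuration enzyme, at 4.37 ± 0.12 (SE), and the list was called after quantile normalization (adjusted p = 0.0174) and centring (adjusted p = 0.00249), against adjusted p = 0.0914 as deposited. So were the cancer testis list, with 3 of 7 higher, MAGEB2 at 5.22 ± 0.22 and MAGEC1 at 5.07 ± 0.11 (adjusted p = 0.0117, 0.0127 and 0.0542), and the HOX list, with 7 of 11 higher, HOXB9 at 5.37 ± 0.09, and the HOX cofactor PBX3 lower at -4.73 ± 0.15 (adjusted p = 0.0105, 0.0127 and 0.0888). STAT5 targets had 9 higher and 3 lower of 16, with the growth factor receptor adaptor GRB10 at 3.86 ± 0.13 and the kinase PIM1 at 3.80 ± 0.16. Cholesterol biosynthesis genes had 11 higher and 1 lower of 23, the desaturase FADS1 at 2.80 ± 0.32. FADS2, the lower 1, at -1.69 ± 0.24, was higher in 1 of 7 laboratories. Heat shock genes had 9 of 16 higher, with BAG3 at 1.49 ± 0.23, and 4 after centring. Immediate early genes had 3 higher and 4 lower of 23. DUSP1, at 1.07 ± 0.29, was higher in 6 of 7 laboratories and was not called after quantile normalization. CCN1, at 0.88 ± 0.14, was not called under either other scaling. The immediate early list was called over the clusters above the median mean signal (adjusted p = 0.0201, against 0.0914).

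Markers of other blood lineages and tissues gave mixed calls. There were 6 higher and 1 lower of 16 for megakaryocytes, 2 and 2 of 21 for granulocytes and monocytes, 3 and 2 of 23 for T and NK cells, and 8 and 1 of 19 for fibroblasts and epithelia. LYZ, lysozyme, at 4.47 ± 0.27 (SE), CD3D, a T-cell receptor chain, at 3.82 ± 0.27, and EPCAM, an epithelial adhesion molecule, at 5.24 ± 0.09, were higher in K562. Calls were 6 higher and 2 lower of 19 for ERK output, 4 and 1 of 25 for hypoxia, 1 and 1 of 18 for the unfolded protein response, and 3 and 1 of 10 for metallothioneins and oxidative stress. Of 30 ribosomal protein genes 6 were higher. Of 11 housekeeping genes 2 were higher, GUSB at 0.79 ± 0.10 and TBP at 0.78 ± 0.15, both uncalled under either other scaling, and 2 were lower, ACTB at -3.50 ± 0.12 and B2M at -2.21 ± 0.11. The median, mean and test differed in sign for the megakaryocyte list (-0.0028, 0.61 and up), ERK output (0.26, 0.40 and down) and housekeeping (0.18, -0.30 and down). In all 29 lists the counts adjusted over the list alone were the same as those over all clusters. With an estimated correlation, camera called 2 of the 29 lists, B cell and NF-kB.

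**Figure D1:**
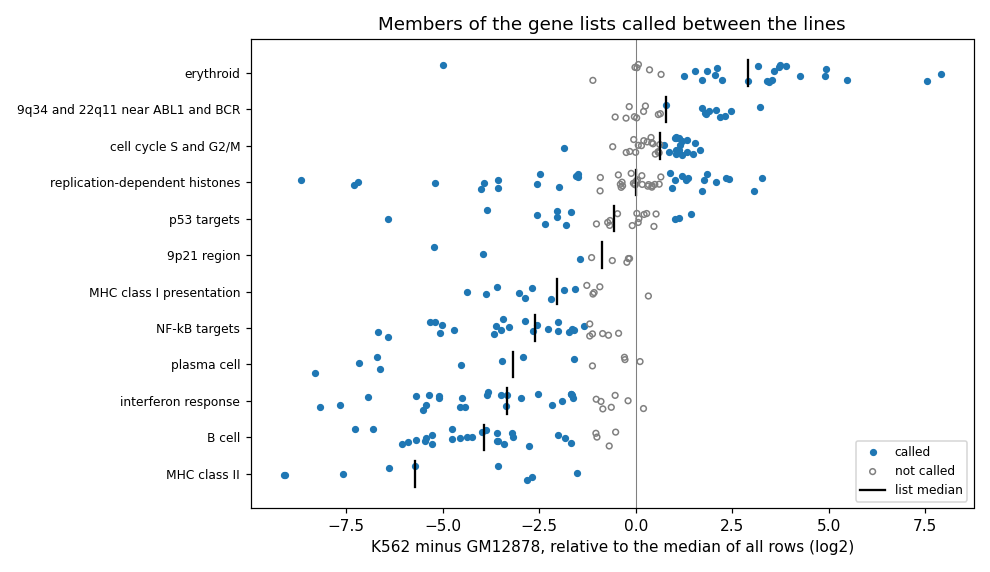
Difference between K562 and GM12878 (log2, relative to the median of all clusters) of each measured member of the 12 gene lists called by camera, with 1 point per gene, filled where called, and a bar at the list median. The floor of 1 for a call applied to the difference before the median shift of 0.33 was taken off. All 9 MHC class II genes and 26 of 30 B-cell genes lie to the left as called members, and 22 of 29 erythroid genes to the right.

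Chromosome by chromosome, genes on chromosomes 13 and 14 were lower in K562, with medians of -0.19 over 256 genes and -0.13 over 459 genes (camera adjusted p = 0.0037 and 0.0325). Neither was called with an estimated correlation (adjusted p = 0.994 with an estimated correlation for both).

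Among K562 cells, those from Washington stood apart in the genes that varied most between laboratories. CXCL11, a chemokine induced by interferon, was lowest there at 2.69 ± 0.74 (SD, n = 3 arrays, as below) and highest at Stanford, with a range of 5.31 (adjusted p = 0.000849). DAB2, an endocytic adaptor, was lowest at Washington at 3.81 ± 0.17 and highest at Yale at 8.70 ± 0.52 (adjusted p = 9.7e-14). The linker histone gene H1-5 ran from 4.47 ± 0.21 at Washington to 9.09 ± 0.18 at Duke (adjusted p = 2.33e-06), and CYB5A, cytochrome b5, from 3.76 ± 0.31 at Washington to 8.21 ± 0.31 at Albany (adjusted p = 5.58e-07). CPVL, a carboxypeptidase, was highest at Washington, at 8.07 ± 1.23, against 4.09 ± 0.23 at Stanford (adjusted p = 4.3e-08). The others among the 10 widest ranges were ABRACL, TCN1, which carries vitamin B12, FAM111A, MAGEA1 and the G protein subunit GNG12. Within the second run, which holds 2 of the 3 arrays from Washington, CPVL, CYB5A and ABRACL were not called and the other 7 were. Limma's F-test over the 7 laboratories called 2151 clusters in K562. It called 1292 without replicate 2 of K562 Albany, 844 with the arrays of this line alone, 314 within the first normalization run and 263 within the second.

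Among GM12878 cells, those from Yale stood apart. They were lowest in 8 of the 10 genes with the widest range. GTSF1, a piRNA pathway factor, stood at 2.86 ± 0.35 at Yale and 8.68 ± 0.26 at Stanford (SD, n = 3 arrays each; adjusted p = 6.14e-11). TMPRSS3, a serine protease, was at 3.83 ± 0.13 at Yale, and TCL1A, an AKT coactivator of early B cells, at 4.55 ± 0.31, against 8.74 ± 0.26 at Stanford (adjusted p = 2.69e-07). SEL1L3, the GTPase RAB31, GPR160, TEX9 and FAM30A were the other 5. DNAJB1, a heat shock cochaperone, was highest at Yale, at 11.35 ± 0.13, against 7.03 ± 1.08 at Albany (adjusted p = 6.97e-08). ENPP2, which makes lysophosphatidic acid, ran from 4.76 ± 0.87 at Stanford to 9.03 ± 0.40 at Washington (adjusted p = 2.02e-09). The F-test called 3626 clusters, and 6093 without replicate 1 of GM12878 Albany. Within the second run it called 3679. The first run holds no array from Yale or Affymetrix and 1 each from Broad, Stanford and Washington, too few to weigh a count. Clusters called in both lines numbered 608, against 354 for independent lists. Both tests share each cluster's residual variance, so some excess is built in.

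The difference between the lines itself varied between laboratories for 1192 clusters by the F-test of the interaction, and for 2008 without replicate 1 of GM12878 Albany. The differences by laboratory in this paragraph are as measured and not relative to the median of all clusters. The widest range, 6.52, was that of FYB1, an adaptor of immune cells (adjusted p = 0.000184). It was 4.56 higher in K562 among the cells from Yale, and its difference was -1.96 at Washington. GTSF1 was 8.77 higher in K562 at Yale and 2.94 higher at Stanford (adjusted p = 1.77e-07). TEX9 differed by 0.77 at Yale and by -4.04 at Duke (adjusted p = 4.73e-05). MACC1, a regulator of the receptor MET, differed by 0.65 at Stanford and by -5.29 at Washington (adjusted p = 2.59e-05). The others among the 10 widest were TC2N, CYB5A, SEL1L3, TMPRSS3, DAB2 and H1-5, each with its extreme at Yale, Washington or both.

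Set against the other 6 laboratories, K562 from Washington had lower integrated stress response, hypoxia and histone genes. Of 33 stress response genes 12 fell below the other laboratories, 13 adjusted over the list alone, with a median of -0.85. DDIT4, an inhibitor of mTORC1, was lower by -2.72 ± 0.35 (SE), SLC7A11, the cystine transporter, by -2.38 ± 0.50, and ASNS, asparagine synthetase, by -1.96 ± 0.23. Camera gave adjusted p = 8.09e-22, and adjusted p = 0.387 with an estimated correlation. The per-array list means differed by -1.02 (two-sided exact permutation p = 0.00226, 3 arrays against 18), by -0.71 within the first run (1 array of this group, and 11 splits, too few for a p under 0.05) and by -1.23 within the second (exact p = 0.0222, the smallest that 45 splits allow). Without the 7 arrays of low upper quartile, 1 of them from this group, 4 members were called, and the list median was -0.76. In hypoxia genes 6 of 25 fell, 8 adjusted over the list alone, with the mitophagy receptor BNIP3 at -2.47 ± 0.57 and the aldolase ALDOC at -2.26 ± 0.34 (adjusted p = 1.34e-07, adjusted p = 0.679 with an estimated correlation), and 3 without the low arrays. The exact p of the hypoxia means was 0.0222 within the second run. In all, 10 of the 29 lists had their lowest K562 mean at Washington, among them housekeeping at 8.88 ± 0.66 (SD), with replicate 2 at 8.11 and 1 of 11 members called lower (adjusted p = 0.075), and cell cycle at 8.60 ± 0.64, with no member called (adjusted p = 0.00324, adjusted p = 0.918 with an estimated correlation).

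Of 50 histone genes 5 fell in K562 from Washington, 6 adjusted over the list alone, with H1-5 at -3.71 ± 0.37 (SE) and H2AC16 at -2.63 ± 0.40 (adjusted p = 1.92e-06, adjusted p = 0.785 with an estimated correlation). This list was not called within the first run (adjusted p = 0.0708), and its means had an exact p of 0.0444 within the second. Immediate early genes had 3 of 23 lower, 4 adjusted over the list alone, the phosphatase gene DUSP1 at -1.11 ± 0.23 and KLF6 at -1.08 ± 0.25 (adjusted p = 4.42e-07, adjusted p = 0.398 with an estimated correlation). The count was 1 after quantile normalization, 0 without the 7 arrays of low upper quartile and 1 under a second limit that leaves out 6. The list median was -0.46 with all arrays, and -0.36, -0.47 and -0.50 in these settings. Erythroid genes had 4 of 29 lower, 4 adjusted over the list alone, with carbonic anhydrase CA1 at -2.70 ± 0.44 and AHSP, the alpha globin chaperone, at -1.67 ± 0.32 (adjusted p = 0.00851, adjusted p = 0.918 with an estimated correlation). The exact p of the immediate early means was 0.018 over all arrays and 0.0444 within the second run, and that of the erythroid means 0.0992 and 0.289. The erythroid count was 1 without the 7 low arrays and 2 under the second limit. This list was not called within the second run (adjusted p = 0.322) or over the clusters above the median mean signal (adjusted p = 0.785). Limma called 308 clusters for K562 from Washington, 83 higher and 225 lower, and 715 without its replicate 1. CPVL was higher by 3.49 ± 0.27 and ABRACL by 3.08 ± 0.52, and CXCL11 was lower by -4.31 ± 0.65. Within the second run 152 were called.

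**Figure D2:**
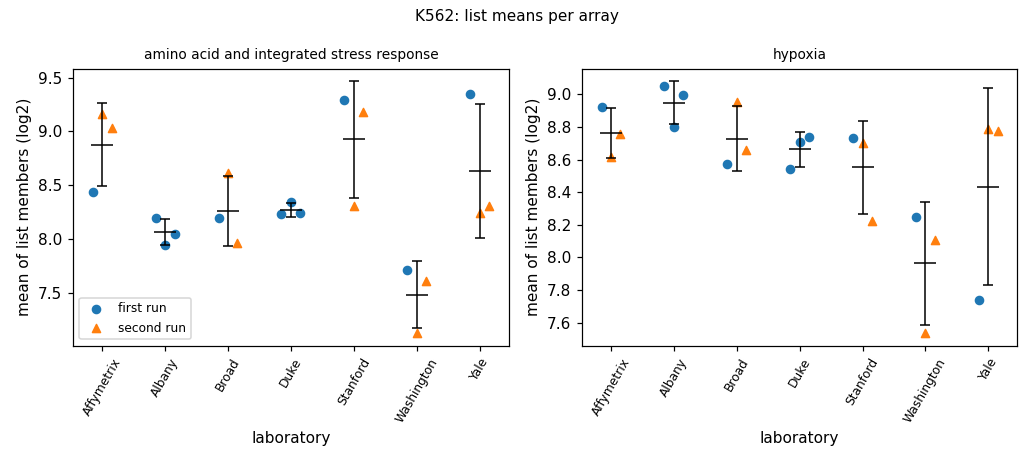
Mean log2 signal over the members of 2 gene lists on each K562 array, by laboratory, with 1 point per array (circle, the first normalization run; triangle, the second) and bars at the mean ± SD of 3 arrays. The stress response list averaged 7.48 ± 0.31 at Washington and the hypoxia list 7.96 ± 0.38.

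K562 from Affymetrix had higher immediate early genes, and 13 of the 29 lists had their highest K562 mean there. Of 23 measured, 6 rose above the other laboratories, 6 adjusted over the list alone, among them DUSP1 by 1.99 ± 0.23 (SE), the AP-1 subunit gene JUN by 1.38 ± 0.24 and the stress-induced factor ATF3 by 1.31 ± 0.26. Camera gave adjusted p = 1.89e-14, and adjusted p = 0.238 with an estimated correlation, and the list means differed by 0.67 (exact p = 0.00226, 3 arrays against 18). Within the first run, with 1 array of this group, they differed by 0.26 (11 splits, too few for a p under 0.05), and within the second by 0.87 (exact p = 0.0222, 45 splits). Limma called 123 clusters, 90 higher and 33 lower, or 75 and 57 after centring. The count was 48 with the arrays of the line alone, 218 without the arrays of low upper quartile, 192 under the second limit and 6 within the first run. It called 525 without replicate 1, 16 without replicate 2 and 19 without replicate 3. FTL, the ferritin light chain, stood at 9.73 ± 1.10 (SD) against 7.73 elsewhere, and DOK3, an adaptor of immune receptors, was lower by -1.65 ± 0.38. NUPR1, a stress-induced chromatin protein, differed by 2.32 ± 0.63 and SCG3, a secretogranin, by -2.19 ± 0.52, and both had the opposite sign within the first run, at -0.79 and 0.52.

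In K562 from Albany, 3 erythroid and 3 hypoxia genes were called higher, while 10 of the 29 lists had their lowest K562 mean there. As wholes, the erythroid and hypoxia lists passed camera at the preset correlation but not with an estimated correlation, by fry or by exact tests. The median of all clusters was -0.21 there, and differences are relative to it. Erythroid genes had 3 of 29 higher, 4 adjusted over the list alone, among them AHSP by 2.39 ± 0.32 (SE) and the mitochondrial iron importer SLC25A37 by 1.54 ± 0.21 (adjusted p = 2.88e-10, adjusted p = 0.398 with an estimated correlation). Hypoxia genes had 3 of 25 higher, 3 adjusted over the list alone, BNIP3 by 2.15 ± 0.57 and NDRG1 by 1.90 ± 0.30 (adjusted p = 1.06e-11, adjusted p = 0.398 with an estimated correlation). The exact p over list means was 0.114 for the erythroid list and 0.0647 for hypoxia, 3 arrays against 18, and 0.345 and 0.0727 within the first run, which holds all 3. With the deposit block as a term 1 hypoxia gene was called. Leaving out the 7 arrays of low upper quartile keeps 1 array of this group. The list medians as measured were then 0.33 and 0.47, against 0.25 and 0.37 with all arrays. Under the second limit, which leaves 2 of its arrays, 3 erythroid members and 1 hypoxia member were called. Limma called 568 clusters, 33 higher and 535 lower. The split was 70 and 117 after quantile normalization and 66 and 172 after centring. The count was 225 within the first run, 54 with the upper quartile as a covariate and 164 under the second limit. Limma called 0 without the 7 low arrays, against 5859 clusters at an unadjusted p under 0.05 with all arrays. Without replicate 1 it called 1348, without replicate 2 it called 15 and without replicate 3 it called 86. ABRACL was lower by -2.62 ± 0.52 and the small GTPase RAP1B by -2.23 ± 0.68.

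K562 from Yale had 500 clusters higher and 28 lower. IGF1, insulin-like growth factor 1, was higher by 2.51 ± 0.23 (SE; adjusted p = 4.04e-08) and AHSP lower by -1.79 ± 0.32 (adjusted p = 0.00106). PLA2G4A, a phospholipase, differed by 2.78 ± 0.47 and POPDC3 by -1.54 ± 0.36, with -0.045 and 0.77 within the first run, which holds 1 array of this group. Limma's total of 528 became 873 without replicate 1, 172 without replicate 2 and 74 without replicate 3, 178 within the second run and 350 with the upper quartile as a covariate.

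Fewer clusters were called for K562 from Stanford, Duke and the Broad Institute. The Stanford count was 58, with NEBL, nebulette, higher by 2.41 ± 0.50 (SE). It was 147 without K562 Stanford replicate 1, 33 without its replicate 2, 7 without its replicate 3 and 127 without K562 Yale replicate 1. It was 31 within the second run, 89 with the upper quartile as a covariate, 19 without the arrays of low upper quartile and 33 under the second limit. Limma called 0 for Stanford within the first run and with the arrays of the line alone, against 1768 at an unadjusted p under 0.05 with all arrays. The Duke count was 17, with EPHB6, an Eph receptor without kinase activity, higher by 2.01 ± 0.23 and PYGL, glycogen phosphorylase, lower by -1.84 ± 0.22. It was 7, 3 and 5 without replicates 1, 2 and 3 of K562 Duke, 10 and 9 without replicates 2 and 3 of K562 Albany, and 77 and 10 without replicates 1 and 3 of K562 Affymetrix. It was 46 and 11 without replicates 1 and 3 of K562 Yale, 49 without K562 Washington replicate 1 and 11 without K562 Stanford replicate 3. It was 6 with the deposit block as a term, 45 with the covariate, 11 without the low arrays under either limit and 4 with the arrays of the line alone. The Broad count was 7, with the iron exporter SLC40A1 higher by 1.09 ± 0.24, and was 37, 0 and 19 without replicates 1, 2 and 3 of K562 Broad. It was 3, 1 and 1 without replicates 1, 2 and 3 of K562 Duke, 22, 3 and 2 without those of K562 Yale and 3, 19 and 3 without those of K562 Stanford. It was 4 and 2 without replicates 2 and 3 of K562 Affymetrix, and 1 without K562 Albany replicate 2. With the deposit block as a term it was 11, and it was 4 without the low arrays and 3 under the second limit. After quantile normalization, within either run and with the arrays of the line alone limma called 0 for the Broad Institute, with 1766 clusters at an unadjusted p under 0.05 as deposited.

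GM12878 from Yale had lower interferon, B-cell and cholesterol synthesis genes and higher heat shock genes. Of 32 interferon genes 19 fell below the other laboratories and 1, the guanylate-binding protein GBP4, rose by 1.03 ± 0.31 (SE), the same counts adjusted over the list alone, with a list median of -1.10. IFIT1, which binds viral RNA, was lower by -3.02 ± 0.32 and IFI6 by -2.92 ± 0.36. Camera gave adjusted p = 3.23e-16, and adjusted p = 0.387 with an estimated correlation. The list means differed by -1.21 (two-sided exact permutation p = 0.000877, 3 arrays against 17) and by -1.25 within the second run (exact p = 0.00606), both the smallest that 1140 and 165 splits allow. Of 30 B-cell genes 10 fell, 10 adjusted over the list alone, with TCL1A at -3.51 ± 0.33 and the complement receptor CR2 at -3.15 ± 0.24 (adjusted p = 7.61e-06, adjusted p = 0.641 with an estimated correlation). The B-cell list was not called over the clusters above the median mean signal (adjusted p = 0.357). The list means of the B-cell and cholesterol lists gave the same exact p, 0.00606, within the second run. Of 23 cholesterol synthesis genes 9 fell, 9 adjusted over the list alone, with the sterol oxidase MSMO1 at -2.03 ± 0.46 and the desaturase SCD at -1.73 ± 0.22 (adjusted p = 3.86e-07, adjusted p = 0.756 with an estimated correlation), and 5 with the upper quartile as a covariate. In all, 18 of the 29 lists had their lowest GM12878 mean at Yale, so the fall was not confined to these 3. Among the 18 were NF-kB, hypoxia, ribosomal proteins, class I presentation and housekeeping. The last 2 stood at 8.13 ± 0.17 (SD) against 8.49 to 9.11 elsewhere for class I, with 2 of 14 members called lower (adjusted p = 0.00224, adjusted p = 0.790 with an estimated correlation), and 8.76 ± 0.36 against 9.02 to 9.45 for housekeeping, with 1 of 11 called lower (adjusted p = 0.242, adjusted p = 0.918 with an estimated correlation) and the lowest array, replicate 1, at 8.37.

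Heat shock genes had 4 of 16 members higher in GM12878 from Yale, 4 adjusted over the list alone, DNAJB1 by 3.41 ± 0.30 (SE) and the chaperone HSPH1 by 1.81 ± 0.38 (adjusted p = 2.43e-07, adjusted p = 0.398 with an estimated correlation). Immediate early genes had 4 of 23 higher, 4 adjusted over the list alone, with EGR1 at 1.30 ± 0.45 and PPP1R15A, which restarts translation after stress, at 1.30 ± 0.20 (adjusted p = 5.19e-05, adjusted p = 0.641 with an estimated correlation). ERK output genes had 5 of 19 higher, 5 adjusted over the list alone, PHLDA1 by 1.69 ± 0.21 and SPRY2, a feedback inhibitor, by 1.68 ± 0.26 (adjusted p = 0.00134, adjusted p = 0.641 with an estimated correlation). Within the second run, which holds all 3 Yale arrays, the list means of these 3 lists differed by 0.61 (exact p = 0.0727), 0.24 (exact p = 0.285) and 0.23 (exact p = 0.255), none of which passes 0.05. Limma called 1336 clusters for this group, 343 higher and 993 lower, a split of 621 and 692 after quantile normalization and 559 and 669 after centring. The mucin gene MUC13 was higher by 3.22 ± 0.23, and GTSF1 and TMPRSS3 were lower by -4.67 ± 0.29 and -3.82 ± 0.18.

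In GM12878 from Washington, interferon genes were higher. Of 32 measured, 15 rose, 15 adjusted over the list alone, with a median of 0.95. PARP9, a partner of the ubiquitin ligase DTX3L, was higher by 1.90 ± 0.35 (SE) and HERC6 by 1.86 ± 0.19. Camera gave adjusted p = 1.33e-14, and adjusted p = 0.393 with an estimated correlation, and the list means differed by 0.93 (exact p = 0.00877, 3 arrays against 17). Within the first run they differed by 0.82 (9 splits, too few for a p under 0.05) and within the second by 1.06 (exact p = 0.0545, 55 splits). The count was 9 after quantile normalization, and 10 with the upper quartile as a covariate or without the arrays of low upper quartile. Heat shock genes had 4 of 16 higher, 5 adjusted over the list alone, with the cochaperones STIP1 at 1.24 ± 0.23 and HSPA4 at 1.23 ± 0.27 (adjusted p = 0.001, adjusted p = 0.785 with an estimated correlation), 2 after quantile normalization, 1 without the low arrays and none with the covariate. The exact p of the heat shock list means was 0.0263 over all arrays and 0.164 within the second run. Limma called 500 clusters, 471 higher and 29 lower, or 267 and 69 after quantile normalization. The count was 873 within the second run, 227 with the upper quartile as a covariate, 287 without the arrays of low upper quartile and 292 under the second limit. Limma called 0 within the first run, with 1 array of this group, against 4594 at an unadjusted p under 0.05 with all arrays. It called 839 without replicate 1, 229 without replicate 2 and 184 without replicate 3. CMA1, mast cell chymase, was higher by 3.43 ± 0.16, F13A1, a coagulation factor subunit, by 3.03 ± 0.40, and EGR1 lower by -1.72 ± 0.45.

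**Figure D3:**
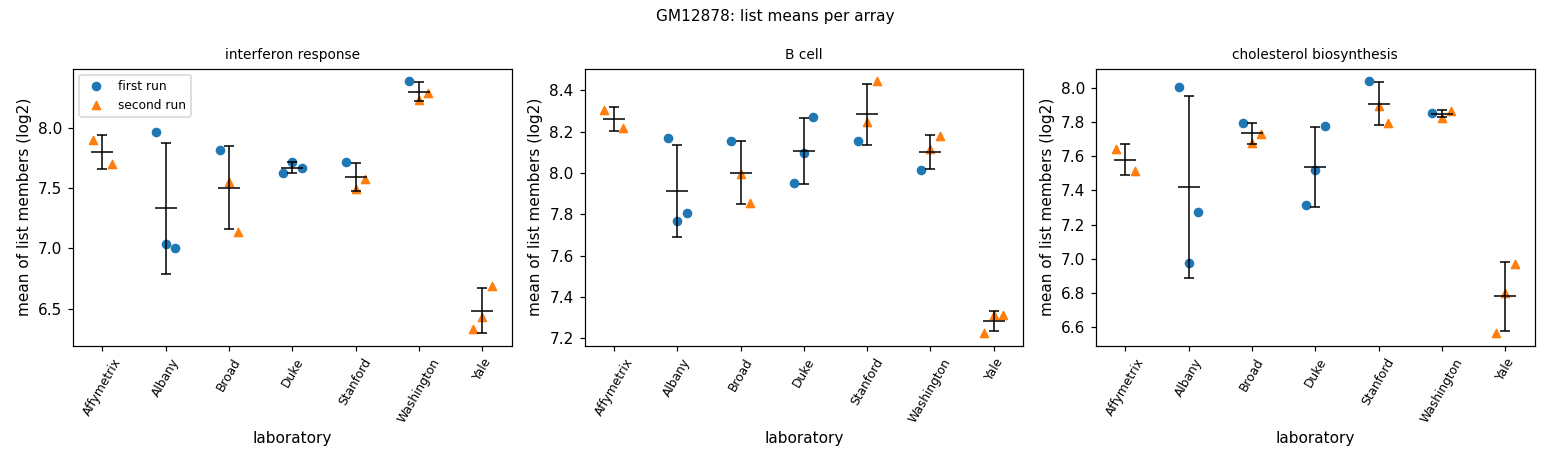
Mean log2 signal over the members of 3 gene lists on each GM12878 array, by laboratory, with 1 point per array (circle, the first normalization run; triangle, the second) and bars at the mean ± SD of 3 arrays (2 for Affymetrix). The 3 arrays from Yale are the lowest in each panel, with means of 6.48 ± 0.19 for interferon, 7.28 ± 0.05 for B cell and 6.78 ± 0.20 for cholesterol, and the 3 from Washington are the highest for interferon, at 8.30 ± 0.08.

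GM12878 from Affymetrix, with 2 arrays, had 4 of 23 immediate early genes higher, 5 adjusted over the list alone, with the nuclear receptor NR4A1 at 1.35 ± 0.19 (SE) and CSRNP1 at 1.27 ± 0.19 (adjusted p = 1.98e-09, adjusted p = 0.387 with an estimated correlation), and 2 after quantile normalization. The list means differed by 0.56 (exact p = 0.00526, 2 arrays against 18), and by 0.48 within the second run, which holds both (exact p = 0.0727, 55 splits) and does not pass 0.05. Limma called 81 clusters, 79 higher and 2 lower, or 55 and 8 after quantile normalization. It called 48 with the deposit block as a term, 43 after centring and 51 with the arrays of the line alone. It called 31 without replicate 1, 6 without replicate 2 and 157 without GM12878 Albany replicate 1. LZTFL1, a regulator of ciliary trafficking, was higher by 2.15 ± 0.45 and TMPRSS3 by 2.08 ± 0.22.

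In GM12878 from Albany the chemokine genes CXCL9 and CXCL10 were higher. Differences are relative to a median of -0.11 over all clusters. CXCL9 was higher by 2.31 ± 0.44 (SE; adjusted p = 0.0127) and CXCL10 by 1.73 ± 0.37 (adjusted p = 0.0209), and DNAJB1 was lower by -1.51 ± 0.30 (adjusted p = 0.0108). The 3 arrays differed widely among themselves, with an SD of 2.36 for CXCL9. None of these 3 genes was called with the arrays of this line alone, with the deposit block as a term, within the first run, with the upper quartile as a covariate or without the arrays of low upper quartile. Limma called 220 clusters, 20 higher and 200 lower, or 90 and 172 after quantile normalization and 44 and 160 after centring. It called 2313 without replicate 1. Without replicate 2, without replicate 3, with the deposit block as a term and with the upper quartile as a covariate it called 0, against 5167 clusters at an unadjusted p under 0.05 with all arrays. It called 0 within the first run and with the arrays of the line alone as well, and without the low arrays it called 7, or 11 under the second limit. Leaving out GM12878 Affymetrix replicate 2, Broad replicate 2 or Washington replicate 3 gave 136, 139 and 143.

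Among the other GM12878 cells, those from Stanford were higher in SEL1L3 by 2.14 ± 0.34 (SE) and in GTSF1 by 2.12 ± 0.29, and lower in ENPP2 by -2.37 ± 0.25. The Stanford count was 77, and 36 without its replicate 2 and 24 without its replicate 3. It was 256 within the second run and 41 with the arrays of the line alone. The first run holds 1 array of GM12878 Stanford, too few to weigh a count there. Cells from Duke were higher in the histone gene H4C13 by 1.76 ± 0.41 and in CD1C, which presents lipid antigens, by 1.55 ± 0.35. Their count was 78, 29 higher and 49 lower, or 26 and 76 after quantile normalization and 11 and 54 after centring. It was 3, 2 and 290 without replicates 1, 2 and 3 of GM12878 Duke, 172 and 47 without replicates 1 and 3 of GM12878 Washington, 48 without GM12878 Affymetrix replicate 2, 50 without GM12878 Yale replicate 3 and 49 without GM12878 Stanford replicate 2. It was 2 with the deposit block as a term, 3 with the arrays of the line alone, 201 with the upper quartile as a covariate, 472 without the arrays of low upper quartile and 457 under the second limit. For Duke limma called 0 within the first run, which holds all 3 of its arrays, against 4282 at an unadjusted p under 0.05 with all arrays. Cells from the Broad Institute were higher in TNFRSF19, a TNF receptor family member, by 1.17 ± 0.17 and lower in PTPN13, a tyrosine phosphatase, by -1.79 ± 0.27. Their count was 12, 4 higher and 8 lower, or 12 and 13 after quantile normalization. It was 144 without GM12878 Broad replicate 1, 1 without its replicate 3, 28 without GM12878 Albany replicate 1 and 30 without GM12878 Washington replicate 1. It was 20 with the deposit block as a term, 21 with the covariate, 3 without the low arrays under either limit, 1 with the arrays of the line alone and 426 within the second run. The first run holds 1 array of GM12878 Broad, too few to weigh a count there.

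Over the 14 laboratories and lines, camera called 91 of 406 pairs of list and laboratory. None was called with an estimated correlation, where 0 of 406 passed. Apart from the class I and housekeeping lists at Yale and the housekeeping and cell cycle lists at Washington, the 17 pairs described above are those with an adjusted p under 0.05 and at least 3 called members, a rule chosen after the table was seen.

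The main axis of spread within each line went with the upper quartile of the arrays. Both summarize the same values, and the sign of the component was set to make r positive over all arrays. The permutation p-values below are thus no independent support. In each line the first principal component, 25.3% of the variance in K562 and 32.9% in GM12878, followed the upper quartile of the array. Pearson's r was 0.826 in K562 (permutation p = 2e-05) and 0.889 in GM12878 (permutation p = 1e-05, the smallest that 100000 resamples allow), and Spearman's rank correlation was 0.879 and 0.856 (permutation p = 1e-05 and 2e-05). All 4 adjusted p were 2e-05. Without the 2 arrays farthest from the median, r was 0.743 and 0.867. Within the first and second runs r was 0.868 and 0.777 in K562 and 0.965 and 0.889 in GM12878. Of the 7 arrays whose upper quartile lay over 0.3 below their run's median, 2 were from K562 Albany, 2 from GM12878 Albany and 1 each from K562 Washington, GM12878 Yale and GM12878 Broad.

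**Figure D4:**
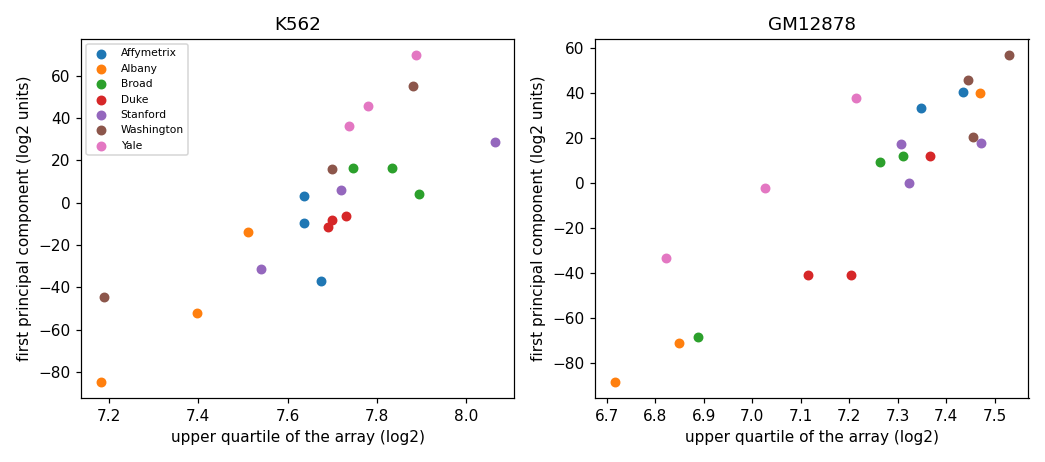
First principal component of the arrays of each line against the upper quartile of the array (log2), 1 point per array, coloured by laboratory. In both panels arrays of higher upper quartile lie higher on the component, with r of 0.826 over 21 K562 arrays and 0.889 over 20 GM12878 arrays.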

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

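The splits of the arrays without regard to the runs and the tests of the laboratories' share of the main axis and of interferon genes in K562 were planned, and the tests of array-wide signal, of separate runs, of handling for the cholesterol and stress response lists and of mixed RNA and the splits within the runs were chosen after the results were seen. Over 98 sets of 7 laboratories, 13 had a laboratory far from the other 6 by Dixon's test, whose rate by chance is about 1 in 20. That rate applies to the 58 list means, of which 4 passed against 2.9 by chance. It does not apply to the 20 genes named for their wide range, of which 7 passed, nor to the 20 genes named for their difference between the lines, of which 2 passed.

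GM12878 from Yale lay below the other laboratories in the B-cell list mean (7.28), the 9p21 list mean (4.55), GTSF1 (2.86), TCL1A (4.55) and TEX9 (2.72), and above them in DNAJB1 (11.35). The difference between the lines was also nearest to 0 at Yale for MX1 (-6.27) and IFI44L (-5.82), as measured and not relative to the median of all clusters. K562 from Washington lay below the others in CXCL11 (2.69) and FAM111A (3.55) and above them in CPVL (8.07). The T and NK list mean stood apart in K562 from Stanford (4.10), and the STAT5 list mean in GM12878 from Affymetrix (6.59).

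The difference between the lines varied between laboratories for 1192 clusters. The widest ranges of that difference were 6.52 for FYB1, 5.94 for MACC1, 5.83 for GTSF1, 5.45 for TC2N and 5.12 for CYB5A. Those of SEL1L3, TEX9, TMPRSS3, DAB2 and H1-5 were 5.07, 4.81, 4.81, 4.74 and 4.74.

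Of 17 pairs of list and laboratory that stood apart, 12 differed between the lines there, by camera, run with the preset correlation alone. The 5 that did not were erythroid (adjusted p = 0.141) and immediate early (adjusted p = 0.457) at Washington, ERK output at Yale (adjusted p = 0.101) and immediate early at Affymetrix for each line (adjusted p = 0.425). The lists were picked for standing apart on the same arrays. At Yale the adjusted p of the others was 0.00251 for B cell, 1.26e-11 for interferon, 7.62e-08 for immediate early, 1.26e-06 for heat shock and 8.89e-08 for cholesterol. At Washington it was 1.14e-10 for the stress response, 0.000469 for hypoxia, 0.000469 for histones, 1.26e-11 for interferon and 0.00349 for heat shock. At Albany it was 3.16e-06 for the erythroid list and 4.27e-07 for hypoxia.

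The interferon, B-cell and cholesterol lists were lower in GM12878 from Yale, where 18 of the 29 lists had their lowest GM12878 mean, housekeeping (8.76) among them. With the upper quartile of each array as a covariate the interferon median was -1.05, and within the second run the mean difference was -1.25 (exact permutation p = 0.00606). Both argue against array-wide signal and separate runs as the whole cause for interferon genes. The B-cell and cholesterol medians were -0.66 and -0.90 as deposited, -0.54 and -0.68 with the covariate, and -0.68 and -0.91 without the arrays of low upper quartile. Most of either fall thus did not go with the upper quartile, while a broad fall in many lists stays open for both. RNA of K562 mixed into these arrays would bring the 10 named K562 genes near their K562 level, and they lay -7.58 from it, at 2.54 against 2.46 on the other GM12878 arrays. Handling at Yale that acts alike in both lines stays open for the cholesterol list, whose median in K562 was 0.080, since against the other laboratories of its run its mean differed by -0.65 on K562 Yale replicate 1 and by 0.54 on replicates 2 and 3. For interferon genes it stays open too, since only 5 of the 19 lower members had a K562 mean above 6, and a difference between the cultures, untested, may remain.

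The stress response list was lower in K562 from Washington, where 10 of the 29 lists had their lowest K562 mean, housekeeping (8.88) among them. Its median was -0.82 with the upper quartile as a covariate, which argues against array-wide signal as the whole cause. Within the second run the mean difference was -1.23 (exact permutation p = 0.0222). Pairs with over 3 equal values link its 10 arrays, but none shared over 13, so 1 run is not certain. The first run, at -0.71, holds 1 array of this group, so separate runs stay open. Handling at Washington that acts alike in both lines would lower the list in GM12878 too, where its median was 0.040. Handling of the K562 cells alone was not tested, and a difference in the state of those cells when collected may remain, as a hypothesis.

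The main axis of spread between arrays, the first principal component of each line, was set against the signal of the arrays. Its loadings correlated at 0.795 between the lines, across clusters that are not independent replicates, which is consistent with array-wide signal. The share of the axis between laboratories was 60.5% in K562 (permutation p = 0.0216) and 44.2% in GM12878 (permutation p = 0.191). A difference between the laboratories' cells therefore stays open, since 1 line passed and 1 did not.

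Whether chance alone gives such counts was tested on 100 splits of the arrays into groups of the same sizes, the real split included, drawn without regard to the runs. A second set of 100 splits kept the number of arrays of each group in each run. Below, the real count is followed by the highest other count in the first set and in the second. Shares are per contrast, since 100 splits are too few for an adjustment over the 13 contrasts. For the K562 F-test (2151, 426 and 149), the GM12878 F-test (3626, 401 and 2150) and the interaction (1192, 28 and 318), 1 split in each set was as large, the real one, and chance can be excluded. K562 Yale (528, 143 and 503) and K562 Albany (568, 278 and 374) had 1 split as large in each set, the real one. So had GM12878 Washington (500, 285 and 123) and GM12878 Yale (1336, 1004 and 1100). The K562 Albany count was 54 with the upper quartile as a covariate, so it is not set apart from array-wide signal. Splits as large numbered 1 and 2 for K562 Washington (308, 268 and 727) and 2 and 2 for K562 Affymetrix (123, 266 and 178). They numbered 4 and 2 for GM12878 Stanford (77, 473 and 1402). Each of these had another split with more calls than the real one in at least 1 set, so chance is not excluded there.

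For the comparison of the lines (4777), 2 splits were as large, the real one included. The other, with 4987, parted 5 laboratories as the lines do and put both means of the other 2 on 1 side. The next highest gave 3965, and 97 splits gave 0 calls by limma. A split that mixes the lines leaves their difference in the residual spread, which by itself keeps calls low. The counts of 0 are thus no support against chance. Chance cannot be excluded for K562 Broad (7, 174 and 300), K562 Duke (17, 359 and 9), K562 Stanford (58, 1282 and 748) and GM12878 Duke (78, 776 and 832), where 15, 7, 8 and 6 splits of the first set were as large, and 10, 1, 6 and 6 of the second. Nor is it excluded for GM12878 Broad (12, 249 and 553) and GM12878 Albany (220, 1863 and 1002), where 4 and 2 splits of the first set but 10 and 5 of the second were as large. Other splits with several times the real count, as for K562 Stanford, GM12878 Stanford, GM12878 Broad and GM12878 Albany, point to a structure of the arrays beyond these groups. GM12878 from Affymetrix has 2 arrays and was not tested this way.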

How the results depend on the processing

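The settings with a single run, the upper quartile as a covariate and the arrays of low upper quartile left out were chosen after the data were seen, and the second limit on the upper quartile after the counts with the first. Among the main values of the comparisons, 426 alternatives left direction and call or count within 1.5 times, 135 moved a count or value further, 40 lost a call, 17 gained 1 and 4 had the opposite direction. The signal over background limits the dim clusters, and the number of arrays limits every laboratory. The K562 F-test gave 1472 calls without the 7 arrays of low upper quartile and 2128 without the 6 of the second limit, so it depends on which of the 2 limits is used. With the title number as a replicate block in place of the laboratory, the comparison of the lines gave 4832 calls, 3399 higher and 1433 lower. All counts of calls below are limma's. Fry tests a list against 0 and camera against the other genes, and with all clusters at a median of 0.33 higher in K562 a list can pass by fry from that shift alone, so fry is no repeat of a camera call, though its results are in the numbers above. The title numbers do not pair the arrays. The interaction within 1 run was not run, since neither run holds all 7 laboratories in both lines. Where a filter tests fewer clusters or a fit holds fewer arrays, fewer calls follow from that alone in part, and otherwise the cause was not tested.

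Over the clusters above the median mean signal the count was 2898 for the comparison of the lines, 644 for clusters lower in K562, 689 for the interaction, 2561 for all laboratory contrasts, 3 for K562 Broad, 19 for K562 Stanford, 201 for K562 Washington, 176 for K562 Yale, 13 for GM12878 Affymetrix, 6 for GM12878 Broad, 11 for GM12878 Duke, 28 for GM12878 Stanford and 326 for GM12878 Washington. After quantile normalization the count was 1891 for clusters higher in K562, 187 for K562 Albany, 0 for K562 Broad and 25 for GM12878 Broad. After centring each array on its median the count was 2075 for clusters higher in K562, 238 for K562 Albany, 1 for K562 Broad and 43 for GM12878 Affymetrix. With no floor on the difference the count was 14085 for the comparison of the lines, 11472 for clusters higher in K562, 2613 for clusters lower in K562, 11291 for all laboratory contrasts, 389 for K562 Affymetrix, 1840 for K562 Albany, 47 for K562 Broad, 100 for K562 Stanford, 802 for K562 Washington, 1419 for K562 Yale, 131 for GM12878 Affymetrix, 801 for GM12878 Albany, 487 for GM12878 Duke and 184 for GM12878 Stanford. It was 1475 for GM12878 Washington and 3580 for GM12878 Yale. With a floor of log2 2 the count was 1644 for the comparison of the lines, 882 for clusters higher in K562 and 762 for clusters lower in K562. With the arrays of 1 line alone the count was 844 for the K562 F-test, 48 for K562 Affymetrix, 0 for K562 Broad, 4 for K562 Duke, 0 for K562 Stanford, 51 for GM12878 Affymetrix, 0 for GM12878 Albany, 1 for GM12878 Broad, 3 for GM12878 Duke and 41 for GM12878 Stanford.

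With the deposit block as a term the count was 11 for K562 Broad, 6 for K562 Duke, 48 for GM12878 Affymetrix, 0 for GM12878 Albany, 20 for GM12878 Broad and 2 for GM12878 Duke. Without the dimmest of 4 equal parts of the clusters the count was 42 for GM12878 Affymetrix. With an adjusted p under 0.01 the count was 902 for the K562 F-test, 1873 for the GM12878 F-test, 505 for the interaction, 2069 for all laboratory contrasts, 55 for K562 Affymetrix, 197 for K562 Albany, 0 for K562 Broad, 6 for K562 Duke, 15 for K562 Stanford, 184 for K562 Yale, 23 for GM12878 Affymetrix, 0 for GM12878 Albany, 6 for GM12878 Broad and 2 for GM12878 Duke. It was 49 for GM12878 Stanford and 299 for GM12878 Washington. With the upper quartile as a covariate the count was 54 for K562 Albany, 45 for K562 Duke, 89 for K562 Stanford, 350 for K562 Yale, 0 for GM12878 Albany, 21 for GM12878 Broad, 201 for GM12878 Duke and 227 for GM12878 Washington. Without the 7 arrays of low upper quartile the count was 218 for K562 Affymetrix, 0 for K562 Albany, 4 for K562 Broad, 11 for K562 Duke, 19 for K562 Stanford, 7 for GM12878 Albany, 3 for GM12878 Broad, 472 for GM12878 Duke and 287 for GM12878 Washington. Without the 6 arrays of the second limit the count was 192 for K562 Affymetrix, 164 for K562 Albany, 3 for K562 Broad, 11 for K562 Duke, 33 for K562 Stanford, 11 for GM12878 Albany, 3 for GM12878 Broad, 457 for GM12878 Duke and 292 for GM12878 Washington.

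Within the first run the count was 314 for the K562 F-test, 6 for K562 Affymetrix, 225 for K562 Albany, 0 for K562 Broad, 0 for K562 Stanford, 0 for the GM12878 F-test, 0 for GM12878 Albany, 0 for GM12878 Broad, 0 for GM12878 Duke, 0 for GM12878 Stanford and 0 for GM12878 Washington. Within the second run the count was 263 for the K562 F-test, 0 for K562 Broad, 31 for K562 Stanford, 152 for K562 Washington, 178 for K562 Yale, 426 for GM12878 Broad, 256 for GM12878 Stanford and 873 for GM12878 Washington. With an estimated correlation 0 chromosomes were called.

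Within the first run the difference was -0.79 for NUPR1 (K562 Affymetrix), 0.52 for SCG3 (K562 Affymetrix), -0.0447 for PLA2G4A (K562 Yale) and 0.771 for POPDC3 (K562 Yale). With an estimated correlation 2 lists and 0 pairs of list and laboratory were called. With fry 25 lists and 38 pairs were called.

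With an estimated correlation the call was lost for erythroid (adjusted p = 0.142), plasma cell (adjusted p = 0.0893), MHC class II (adjusted p = 0.0893), MHC class I presentation (adjusted p = 0.137), interferon response (adjusted p = 0.142), 9p21 region (adjusted p = 0.0902), 9q34 and 22q11 (adjusted p = 0.138), p53 targets (adjusted p = 0.442), cell cycle S and G2/M (adjusted p = 0.77) and histones (adjusted p = 0.77). With an estimated correlation the call was lost for K562 Affymetrix, immediate early (adjusted p = 0.238), K562 Albany, erythroid (adjusted p = 0.398), K562 Albany, hypoxia (adjusted p = 0.398), K562 Washington, erythroid (adjusted p = 0.918), K562 Washington, immediate early (adjusted p = 0.398), K562 Washington, hypoxia (adjusted p = 0.679), K562 Washington, stress response (adjusted p = 0.387), K562 Washington, histones (adjusted p = 0.785), GM12878 Affymetrix, immediate early (adjusted p = 0.387) and GM12878 Washington, interferon response (adjusted p = 0.393). With an estimated correlation the call was lost for GM12878 Washington, heat shock (adjusted p = 0.785), GM12878 Yale, B cell (adjusted p = 0.641), GM12878 Yale, interferon response (adjusted p = 0.387), GM12878 Yale, ERK output (adjusted p = 0.641), GM12878 Yale, immediate early (adjusted p = 0.641), GM12878 Yale, heat shock (adjusted p = 0.398) and GM12878 Yale, cholesterol (adjusted p = 0.756). Fry did not pass where camera had called, for histones (adjusted p = 0.0693), K562 Albany, erythroid (adjusted p = 0.191), K562 Albany, hypoxia (adjusted p = 0.191), K562 Washington, erythroid (adjusted p = 0.156), GM12878 Yale, ERK output (adjusted p = 0.0756) and GM12878 Yale, immediate early (adjusted p = 0.0758). Fry alone passed for megakaryocyte and platelet (adjusted p = 4.67e-06), fibroblast and epithelial (adjusted p = 4.62e-06), STAT5 targets (adjusted p = 4.67e-06), cancer testis genes (adjusted p = 3.59e-06), HOXA and HOXB (adjusted p = 3.59e-06), heat shock (adjusted p = 0.00188), stress response (adjusted p = 0.000475), cholesterol (adjusted p = 0.00224), ribosomal proteins (adjusted p = 2.76e-05) and metallothionein and oxidative stress (adjusted p = 0.000472). Fry passed as higher in K562, where camera had called nothing and leaned lower, for granulocyte and monocyte (adjusted p = 0.00866), T cell and NK cell (adjusted p = 0.034), ERK output (adjusted p = 0.00133) and hypoxia (adjusted p = 0.034). Over the clusters above the median mean signal the call was lost for cell cycle S and G2/M (adjusted p = 0.0905), K562 Washington, erythroid (adjusted p = 0.785) and GM12878 Yale, B cell (adjusted p = 0.357).

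Over the clusters above the median mean signal the call was gained for immediate early (adjusted p = 0.0201). After quantile normalization the call was lost for histones (adjusted p = 0.15). After quantile normalization the call was gained for cancer testis genes (adjusted p = 0.0117), HOXA and HOXB (adjusted p = 0.0105) and stress response (adjusted p = 0.0174). After centring each array on its median the call was lost for histones (adjusted p = 0.305). After centring each array on its median the call was gained for cancer testis genes (adjusted p = 0.0127), HOXA and HOXB (adjusted p = 0.0127) and stress response (adjusted p = 0.00249). Within the first run the call was lost for K562 Washington, histones (adjusted p = 0.0708). Within the second run the call was lost for K562 Washington, erythroid (adjusted p = 0.322).

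Over the clusters above the median mean signal the share was 38% for cell line, 21% for laboratory and 30.2% for arrays within a group. Over these clusters the mean r was 0.685 for arrays of different lines. Across deposit blocks it was 0.912 in GM12878 and 0.917 in K562 for different laboratories, and 0.944 and 0.926 for the same laboratory. Within a block it was 0.923 and 0.929 for different laboratories, and 0.951 and 0.961 for the same laboratory, in the same order.

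When single arrays, single laboratories (for the comparison of the lines and shares of variance) or 1 replicate of every group were left out, counts ran from 4622 to 5069 for the comparison of the lines, 3113 to 3652 for clusters higher in K562, 1400 to 1509 for clusters lower in K562, 3224 to 6598 for all laboratory contrasts, 6 to 157 for GM12878 Affymetrix, 0 to 2313 for GM12878 Albany, 1 to 144 for GM12878 Broad, 2 to 290 for GM12878 Duke and 24 to 112 for GM12878 Stanford. They ran from 184 to 839 for GM12878 Washington, 1016 to 1415 for GM12878 Yale, 16 to 525 for K562 Affymetrix, 15 to 1348 for K562 Albany, 0 to 37 for K562 Broad, 3 to 77 for K562 Duke, 7 to 147 for K562 Stanford, 206 to 715 for K562 Washington and 74 to 873 for K562 Yale. They ran from 818 to 2008 for the interaction, 2754 to 6093 for the GM12878 F-test and 1292 to 3029 for the K562 F-test, and shares of variance from 33.8 to 37.5% for arrays within a group, 34.5 to 36.7% for cell line, 10.3 to 12.1% for interaction and 15.9 to 19.7% for laboratory. Where 1 array was left in a group, it was assumed to vary like the other groups.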

Other observations

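All values in this part were chosen after the data were seen. The 3 K562 arrays from Yale and from Stanford were not alike in stress genes. The integrated stress response list mean was 9.35, 8.25 and 8.31 on the Yale arrays and 9.29, 8.30 and 9.18 on the Stanford arrays. The hypoxia list mean was 7.74, 8.79 and 8.78 on the same Yale arrays and 8.73, 8.70 and 8.22 on the same Stanford arrays. The array with the highest stress response had the lowest hypoxia mean of its group at Yale and the highest at Stanford. That Yale array is the 1 from the first run. For K562 from Stanford the stress response list had a median of 0.66 above the other laboratories (camera adjusted p = 1.45e-15, adjusted p = 0.398 with an estimated correlation), with no member called over all clusters and 5 called adjusted over the list alone.

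For the cell cycle list of S and G2/M, the median in GM12878 from Albany was -0.53, or -0.42 relative to all clusters. Of its 35 members 2 were called lower (camera adjusted p = 1.15e-05). The list mean was 8.36, 7.01 and 7.06 on replicates 1, 2 and 3, so the difference lies in replicates 2 and 3, which are the Albany arrays of low upper quartile. Their housekeeping means were also lower, at 8.67 and 8.92 against 9.47 on replicate 1, so array-wide signal stays open here. In GM12878 from Washington the median of the list was 0.55, with 2 of 35 members called higher (camera adjusted p = 3.37e-05). Its list mean was 8.49, 8.36 and 8.44 on replicates 1, 2 and 3, and only Stanford replicate 1 lay above all of them, at 8.75. The low Albany arrays enter this contrast, so array-wide signal stays open here too. The Albany and Washington contrasts both had adjusted p = 0.918 with an estimated correlation.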
